A study of Pseudomonas putida with 2 samples.

How the data were processed

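The data were 2 single-colour Agilent arrays of total RNA from Pseudomonas putida isolate NBAII-RPF 9, with 1 array per group. The control culture stood in Luria Bertani (LB) broth, a rich laboratory medium, and the salt shock culture received 1.5 M NaCl for 1 h. The groups were taken from the labels. Per the labels' protocols, the cultures were separate flasks, RNA was isolated with a column kit and checked for quality, and the amplified RNA was labelled with the dye Cy3. The labels disagree on the growth state: the culture is called overnight in the protocol and exponential in a characteristic. The array carries probes of 45 to 60 bases designed on the genome of strain KT2440, per the file headers and descriptions. How far the isolate's sequence differs from KT2440 under these probes was not analysed here.

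The deposited table holds, for each probe and array, a processed signal intensity from Agilent Feature Extraction, per the submitters' processing notes. Its version is not given in the sources used here. Per the notes deposited with the table, the authors' intensity values were background subtracted and dye normalised. No scaling between the arrays was found in them. The lowest value repeated on each array as a floor, 1.40 for 1603 probes (30.1%) on the control array and 1.29 for 911 probes (17.1%) on the salt shock array. The authors also deposited a flag per probe and array, Detected or Compromised. The rule behind the flag is not given in the sources used here, but it followed the signal: the dimmest detected probe had a signal of 6.88 on the control array and the brightest undetected one 6.78, against 6.37 and 5.87 on the salt shock array. The authors' deposited log2 fold equalled the log2 ratio of the signals (salt shock over control) plus a constant of -0.403 for every probe. A further deposited table held the same intensity rounded to at most 0.005 from the signal.

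Of 5337 table rows, 3 were not analysed here. The other 5334 probes covered 5294 gene identifiers, 1468 of them with a gene symbol. The design names 5194 probes specific and 140 cross-hybridising, and 40 genes had 2 probes. The log2 signal of each array was reduced by the log2 of its 75th percentile over all probes, 9.84 for the control array and 13.0 for the salt shock array, which shifted every log2 ratio by -0.406. Probes of a gene were averaged on the log2 scale. A gene was kept when detected on at least 1 array, and counted as higher or lower when its log2 ratio, salt shock minus control, reached 1 or -1, a 2-fold difference. With 1 array per group no test was possible and no p-value is given.

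A gene detected on 1 array alone has only a bound. Its fold was taken between the scaled signal on the array that detected it and, on the other array, the higher of the lowest detected scaled signal and the gene's own signal. The lowest detected scaled signals were -0.52 (log2) on the control array and -1.03 on the salt shock array. No fold is given where the bound fell under 1. A list's or gene's log2 value printed for such genes is the ratio of the measured signals, and is named as not resolved where its bound does not reach 2-fold.

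The 30 gene lists, the naming rule, the scaling, the filter and 19 of the 22 alternatives run were fixed before the data were examined. The lists were compatible solute uptake, compatible solute synthesis, potassium transport, sodium proton antiport, mechanosensitive channels and aquaporins, osmotic and universal stress proteins, chaperones and proteases, cold shock proteins, oxidative stress defence, sigma and anti-sigma factors, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ATP synthase, NADH dehydrogenase and terminal oxidases, the tricarboxylic acid cycle, flagella, chemotaxis, iron, multidrug efflux, porins and outer membrane proteins, alginate and other exopolysaccharides, peptidoglycan and cell division, fatty acids and membrane lipids, glutamate, glutamine and proline, DNA repair, phosphate and pyrroloquinoline quinone, polyhydroxyalkanoate, polyamines, and phage and transposon genes. Membership came from symbols and from patterns in the product descriptions, so some members lie outside their list's theme, many of them in the list of sigma and anti-sigma factors. Each list's median log2 ratio was set among the medians of 10000 random lists of the same size matched on mean signal in 10 bins. That percentile describes these 2 arrays and is not a test of the conditions. Random lists drew genes regardless of position, whereas some lists hold adjacent genes, whose ratios moved together. The percentiles of such lists are therefore likely too extreme. Named genes were the 10 largest rises and 10 largest falls among annotated genes detected on both arrays, and up to 2 genes at least 2-fold higher and 2 at least 2-fold lower per list (or the 1 with the largest ratio where none passed). The 5 largest bounds in each direction among annotated genes were named too. Genes named outside this rule are said to be so.

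The only error that could be measured was between probes of a gene. In the 13 genes whose 2 probes were both detected on both arrays, the log2 ratios had an SD of 0.81, or 0.55 without the most discordant gene, phaC. Each pair set a specific probe against a cross-hybridising one. The steps were tested on simulated data. With a noise SD of 0.8 over 2247 genes, 55.0% of genes raised 2-fold and 46.0% of genes lowered 2-fold passed the threshold, as did 93.0% and 88.0% at 4-fold. Between 9.43% and 11.7% of unchanged genes passed it in each direction. Of 40 random lists of 20 genes, 1 lay outside the central range of the random medians with no shift, and 38 lay below it after a log2 shift of -1 was added.

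The alternatives changed the scaling, the filter, the threshold, the summary of probes, the floor, the trend on signal, list membership and the matching of random lists. The 3 added after seeing the data were bounds in place of ratios, the authors' deposited log2 fold, and the 75th percentile over probes detected on both arrays. A normexp background correction was not run because its input columns were not used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for quantile normalization. Coordinates are those of the KT2440 chromosome in the deposited table, with the lower position first.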

Results

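Gene expression was measured in 1 control culture of Pseudomonas putida NBAII-RPF 9, a bacterium of soil and water, and in 1 culture exposed to 1.5 M NaCl for 1 h, each on 1 array. The control array detected 1705 of 5334 probes (32.0%) and the salt shock array 2181 (40.9%). Of 5294 genes, 1600 were detected on both arrays, 567 on the salt shock array alone, 91 on the control array alone and 3036 on neither. Across the genes detected on both, the arrays correlated with a Pearson r of 0.868 and a Spearman rho of 0.836. These describe genes, which are not replicates.

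The comparison asked which transcripts differed after salt shock. Genes for ribosomal proteins, ATP synthase and flagella had lower scaled signals on the salt shock array, although relative to ribosomal proteins the other groups were higher. The ammonium transporter gene amtB had a 9.54-fold higher scaled signal on its 1 probe. The genes for the small heat shock protein IbpA (4.24-fold), the catalase KatA (4.09-fold) and the superoxide dismutase SodA (3.96-fold) were higher, while those for the chaperones ClpB (at least 10.02-fold) and trigger factor (7.5015-fold) and the superoxide dismutase SodB (2.75-fold) were lower. Among genes detected on both arrays, 144 (9.00%) were at least 2-fold higher after salt shock and 254 (15.9%) at least 2-fold lower, and 20 were at least 4-fold higher against 63 at least 4-fold lower. In simulated arrays with a noise SD of 0.8, between 11.1% and 12.1% of unchanged genes detected on both arrays passed 2-fold upward, and between 8.98% and 10.5% downward. That SD is close to the 0.81 between probes in 13 genes, which was 0.55 without phaC. No simulation was run at 0.55. The simulated unchanged genes also carried no shift, whereas the observed genes detected on both arrays had a median log2 ratio of -0.18. These shares therefore cannot decide how many of the observed changes are noise, nor whether the falls exceed noise more than the rises.

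Over all 2258 genes detected on at least 1 array, 487 were at least 2-fold higher and 342 at least 2-fold lower by their measured signals, so that 58.7% of the differing genes were higher. The excess came from genes detected on 1 array, with 343 higher and 88 lower, since under the 75th percentile scaling those detected on both went the other way. Only 35 of the genes detected on 1 array had a bound of at least 2-fold higher and 37 a bound of at least 2-fold lower, and with bounds in place of ratios the counts were 179 higher and 291 lower (38.1% higher). The split also moved with the scaling. It was 589 to 275 (68.2% higher) when the median of genes detected on both arrays was set to 0, 675 to 243 (73.5% higher) with the 75th percentile of probes detected on both, 723 to 220 (76.7% higher) without scaling, and 2064 to 24 (98.9% higher) with ribosomal proteins set to 0. These splits cover genes detected on at least 1 array. The split of genes detected on both arrays, whose median log2 ratio was -0.18, also rests on the scaling. It was not counted under the other scalings. All directions given are relative to the 75th percentile of each array. Medians of lists close to 0, such as those for chaperones, sigma factors, efflux, potassium, polyamines and NADH dehydrogenase, changed sign under other scalings.

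**Figure D1:**
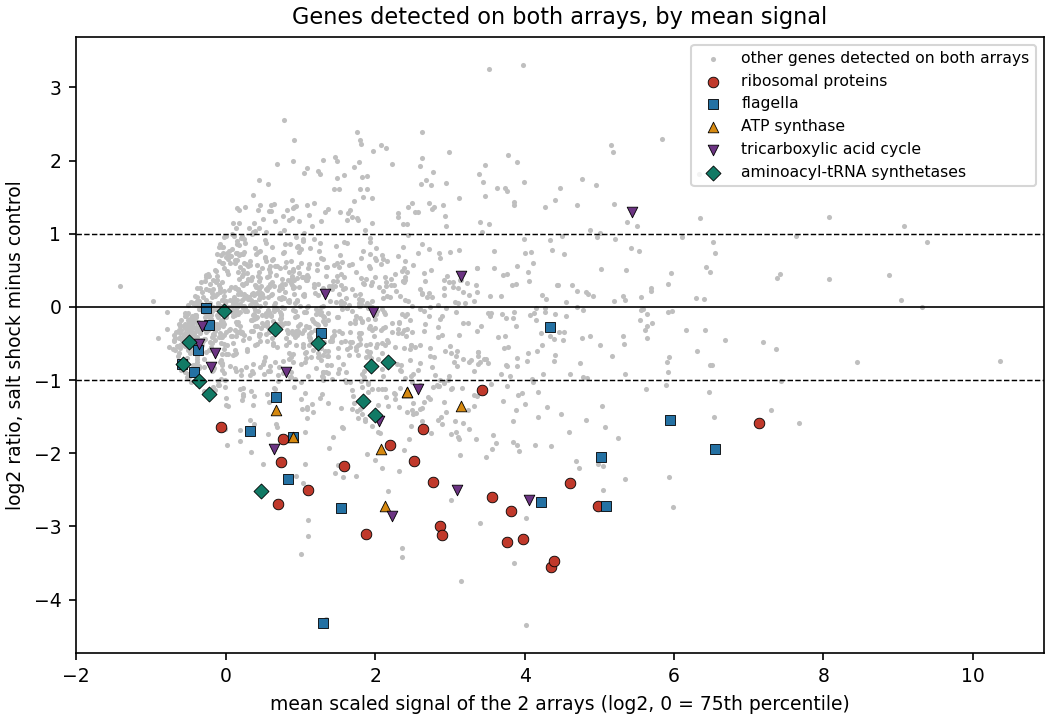
Log2 ratio of salt shock minus control (y axis) against the mean scaled log2 signal of both arrays (x axis) for the 1600 genes detected on both arrays, each point 1 gene, with dashed lines at 2-fold. The 23 ribosomal protein genes shown all lie below the lower line at low and high mean signal alike.

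Genes for ribosomal proteins and aminoacyl-tRNA synthetases were lower as groups. With ribosomal proteins set to 0 the synthetase median turned by construction to 1.76, at percentile 0.40. Of 29 measured ribosomal protein genes, 27 were at least 2-fold lower and 2 higher, with a median log2 ratio of -2.54 (5.81-fold), below the medians of all 10000 random lists. All 23 of those detected on both arrays were lower. The gene rplJ (50S protein L10, position 536457 to 536957) went from a signal of 693 to 77.8, a log2 ratio of -3.56, and rpsS (30S protein S19) had -3.47. The array carries 57 genes of this list, and those not measured were detected on neither array. They include rplB and rplV beside rpsS, with signals of 1.87 and 1.75 on the control array. The group shift therefore covers the measured genes alone. The 2 higher members, rplM and rpmE, were detected on the salt shock array alone and their 2-fold difference was not resolved, though rplM was at least 1.92-fold higher. The gene rpsI adjacent to rplM, named after its value was seen, was lower (a log2 bound of -1.28). Among 13 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 5 were at least 2-fold lower and 1 higher, the median was -0.78 and its percentile 0.485. The lowest were serS (-2.51) and ileS (-1.48), and the higher one, metG, was not resolved. Of 9 translation factor genes 3 were lower and 2 higher, with a median of -0.75 at percentile 2.94, inside the random range, and in the 6 detected on both arrays the median was -1.48 at percentile 0.41. The lower ones included fusA (elongation factor G, -2.20, on a cross-hybridising probe) and nusA, a transcription elongation factor caught by the list's pattern (-2.51). Its higher members efp and PP_0676, the latter a transcription factor of the GreA/GreB family, were not resolved.

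Among annotated genes detected on both arrays, the largest fall was that of the tRNA methyltransferase gene trmD (1669428 to 1670180), which fell from a signal of 718 to 46.8 (log2 ratio -4.35, 20.3-fold), and rimM, which encodes a 16S rRNA processing protein, had -3.51. The termination factor gene rho had -3.75. The other large falls were fliN (-4.33), the rhodanese gene rhdA-2 (-4.27), PP_1816 (a zinc-containing alcohol dehydrogenase, -3.42), PP_1209 (a cold shock domain protein, -3.38) and waaC (a lipopolysaccharide heptosyltransferase, -3.30). Each of these rests on 1 probe. The genes trmD and rimM are adjacent. Other adjacent genes detected on both arrays, named after their values were seen, were lower beside fliN (fliM, -1.55) and rho (ubiD, -1.16). Those beside rhdA-2 (PP_4906, 0.35) and waaC (waaF, -0.10, and waaG, 1.69) did not follow the fall.

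Energy metabolism genes were lower in part. With ribosomal proteins set to 0 the ATP synthase and tricarboxylic acid cycle medians turned by construction to 1.13 and 2.03, at percentiles 0.25 and 1.18. All 7 measured genes of the ATP synthase list were at least 2-fold lower, with a median of -1.41 (2.65-fold) at percentile 0.47. They included atpG, the gamma subunit (-2.72), and atpB (-1.94), whose product description in the table names another protein and whose probe is listed as cross-hybridising. One of the 7 is fliI, an export ATPase of the flagellum. The others lie close together on the chromosome, from atpC to atpI, so they are not independent and the percentile is likely too extreme. In the tricarboxylic acid cycle list 7 of 21 genes were lower and 4 higher, with a median of -0.51 at percentile 1.40, which moved to -0.44 at percentile 8.60, inside the random range, when no filter on dim probes was used. The isocitrate dehydrogenase gene PP_4012 had -2.86 and mdh, the malate dehydrogenase gene, was at least 2.88-fold lower. Its 2 largest rises by signal, PP_2335 (methylcitrate synthase) and leuA (leucine synthesis), lie outside the cycle and were not resolved. The succinyl-CoA synthetase gene sucD, a cycle gene named after its values were seen, was detected on both arrays and higher (1.298, from a signal of 272 to 885). The succinate dehydrogenase genes sdhD (-2.63), sdhB (-2.50), sdhA (-1.94) and sdhC (-1.55), also named after their values were seen, were detected on both arrays and lower. Another lower member, PP_2334 (2-methylisocitrate lyase, -1.12), lies outside the cycle. Among 22 genes of NADH dehydrogenase and terminal oxidases 4 were lower and 4 higher (median -0.21, percentile 10.4), with nuoA at -1.65 and nuoB at -1.64, while the higher PP_0109 and nuoH were not resolved.

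Flagellar genes were lower as a group. Setting ribosomal proteins to 0 adds one constant to every ratio, which turned their median to 1.70 by construction and left its percentile at 0.0. Of 24 measured flagellar genes 11 were at least 2-fold lower and 3 higher, with a median of -0.83 (1.78-fold), below the medians of all 10000 random lists. All 11 lower genes were detected on both arrays, and none of the 3 higher ones was. The motor switch gene fliN (4948859 to 4949344) went from a signal of 109 to 7.21, the export gene flhA had -2.75, and fliA, the flagellar sigma factor gene, had -1.95. The higher genes flgI and fliR were not resolved. Of 11 chemotaxis genes 3 were lower and 1 higher, and the median of -0.75 lay inside the random range (percentile 6.23). The response regulator gene cheY had -2.64, and PP_1371, a chemotaxis transducer, was not resolved, with a bound of 1.68-fold lower. The higher transducer gene PP_2643 was not resolved.

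**Figure D2:**
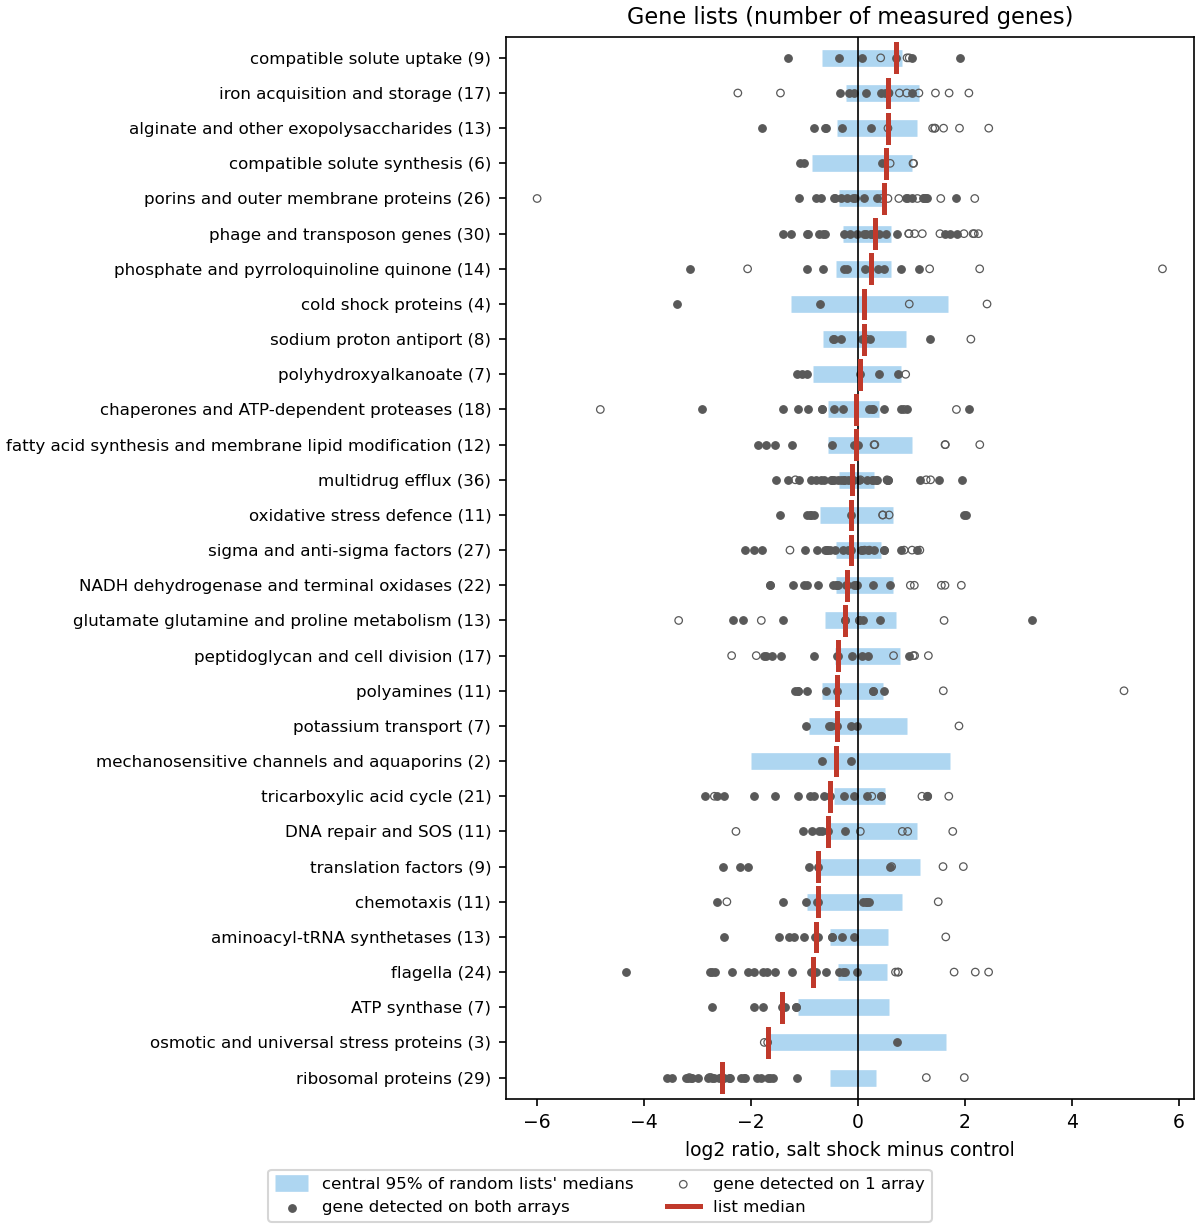
Log2 ratio of salt shock minus control (x axis) for the measured genes of each of the 30 lists (y axis, number of genes in brackets), with filled points for genes detected on both arrays, open points for genes detected on 1 array, a red bar at the list median and a blue band for the central 95% of medians of random lists. The ribosomal protein median of -2.54 lies farthest from its band, and no list median lies above its band. Setting the ribosomal median to 0 adds one constant to every ratio and so turned the ATP synthase, flagella and tricarboxylic acid cycle medians positive by construction.

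Genes for taking up compatible solutes, small molecules that cells gather against osmotic stress, lay inside the range of random lists. Of 9 genes 2 were at least 2-fold higher and 1 lower, with a median of 0.71 (1.64-fold) at percentile 95.6. That median is the value of PP_2182, named after its value was seen. PP_2182 is annotated as an activator of the transporter ProP and was caught by the list's pattern. The list median was -0.08 with no filter on dim probes. Its highest over the settings of scaling, filter, floor, trend and bounds, apart from ribosomal centring, was 1.12. The betaine and proline permease gene PP_0295 (354324 to 355169) went from a signal of 16.6 to 83.3 (1.92), the betaine-binding gene PP_3558 had 1.01, and the transporter gene PP_0869 had -1.30. Of 6 solute synthesis genes 2 were higher and 2 lower (median 0.53, percentile 81.5), and the 3 detected on both arrays had a median of -1.0002 (percentile 12.2). The betaine aldehyde dehydrogenase gene betB stood at -1.0002. The trehalose synthase gene PP_4059 and PP_1481, an aldehyde dehydrogenase, were not resolved, and PP_4431, an ectoine utilisation gene, had -1.07.

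Ion transport lists stayed inside the random range. Of 8 sodium proton antiport genes 2 were higher and none lower (median 0.12, percentile 53.9). The antiporter subunit gene PP_2229 had 1.36, and nhaA2 was not resolved. Of 7 potassium transport genes 1, PP_3953, was higher but not resolved (median -0.39, percentile 14.5). Of 2 genes for mechanosensitive channels neither passed 2-fold (median -0.40, percentile 32.4), and PP_1353 had the larger ratio, -0.67. Of 3 universal stress protein genes, PP_3288 and PP_2187 were lower by signal but their bounds were 1.73- and 1.65-fold. That list's median of -1.68 lay at percentile 2.21, and turned to 0.74 when only its 1 gene detected on both arrays was used.

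Stress defence genes went both ways. Of 11 oxidative stress genes 2 were higher and 1 lower (median -0.12, percentile 38.7), and the 8 detected on both arrays had a median of -0.84 (percentile 3.07). The catalase gene katA rose from a signal of 29.96 to 162 (2.03) and sodA from 17.0 to 89.1 (1.98), while sodB, the gene of another superoxide dismutase, went from 367 to 177 (-1.46). Of 18 chaperone and protease genes 2 were higher and 4 lower (median -0.03, percentile 62.0). The gene ibpA went from 65.6 to 368 (2.08), tig (trigger factor) had -2.91 and clpB, the disaggregase gene, was at least 10.02-fold lower. The other higher member, ccmE of cytochrome c assembly, was not resolved. Of 4 cold shock genes PP_1209 was lower and PP_1099 was higher but not resolved (median 0.13, percentile 20.4). Of 11 DNA repair genes 2 were lower and 1 higher (median -0.56, percentile 2.46), but the 6 detected on both arrays lay at percentile 11.4. The 3 were recA at -1.03, uvrA, not resolved with a bound of 1.57-fold lower, and PP_3255, not resolved.

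Of 27 genes in the sigma and anti-sigma factor list 4 were lower and 3 higher (median -0.13, percentile 23.6). Many of the 27 are not sigma factors but regulators that work with sigma-54, caught by the list's pattern. They include algB among the lower genes and PP_0051 among the higher. The housekeeping sigma factor gene rpoD had -2.11, whereas PP_3086, a sigma-70 factor gene, rose from a signal of 3610 to 10331 (1.11). PP_0051, a regulator that works with sigma-54, was not resolved.

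The outer envelope lists lay inside the random range with all measured genes. Of 26 porin and outer membrane protein genes 9 were higher and 2 lower (median 0.50, percentile 97.1), but in the 16 detected on both arrays, 4 of them higher and 1 lower, the median was -0.07. The porin gene PP_2517 had 1.84 on a cross-hybridising probe, PP_1131, a surface antigen gene, had -1.10, and PP_2702 was at least 12.96-fold lower. PP_1449, a haemagglutinin-type gene, was not resolved, with a bound of 1.62-fold higher. Of 13 alginate and exopolysaccharide genes 6 were higher and 1 lower (median 0.56, percentile 74.1). None of the 6 was resolved, algK and algI (a bound of 1.43-fold higher) among them, the regulator gene algB had -1.78 on a probe with a listed next match of 92.0% identity, and the 6 genes detected on both arrays had a median of -0.61 (percentile 8.29). Of 17 peptidoglycan and division genes 6 were lower and 3 higher (median -0.36, percentile 3.63). PP_4971 (a lytic transglycosylase domain gene) and ftsQ were not resolved, with bounds of 1.65- and 1.71-fold lower, nor were ftsW and murG, of which ftsW had a bound of 1.37-fold higher. Of 12 fatty acid and membrane lipid genes 4 were lower and 3 higher (median -0.03, percentile 31.8), but the 7 detected on both arrays, 4 lower and none higher, had a median of -1.23 at percentile 1.38, below the random range. The acetyl-CoA carboxylase genes accB and accD, of the first step of fatty acid synthesis, had -1.86 and -1.71, and PP_2777 and PP_4379 were not resolved.

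Transport and nutrient lists were mixed. Of 17 iron genes 5 were higher and 2 lower (median 0.57, percentile 61.4), with the receptor genes PP_0525 and PP_2590 among the higher and PP_0350 and PP_4137 the lower, none of these 4 resolved. PP_0525 is annotated as a receptor of the B12 family. The receptor gene oprC, at 1.01, was the 1 rise detected on both arrays and is named after its value was seen. It is not among the list's symbols and entered through its annotation, so its membership does not show a role in iron uptake. Of 36 multidrug efflux genes 5 were higher and 4 lower (median -0.10, percentile 32.0), from PP_1975 at 1.95 and PP_2240 at 1.51 to ttg2A at -1.54 and PP_0589 at -1.30. Of 13 genes for glutamate, glutamine and proline 5 were lower and 2 higher (median -0.23, percentile 19.9). The gene amtB in this list was the largest rise among annotated genes detected on both arrays, from a signal of 36.5 to 462 (3.25, 9.54-fold, 5966352 to 5967683). It rests on 1 probe. The adjacent gene PP_5234, for a nitrogen regulatory protein P-II and named after its values were seen, was at the floor on both arrays (1.40 and 1.29). It therefore gives no ratio to set beside that of amtB. Glutamine synthetase-type genes PP_5184 (-2.32) and PP_3148 (at least 3.96-fold lower, on a cross-hybridising probe with a listed next match of 93.3% identity) were lower, and proC-1, of proline synthesis, was not resolved. Of 14 genes for phosphate and pyrroloquinoline quinone, the cofactor of glucose dehydrogenase, 4 were higher and 2 lower (median 0.25, percentile 74.9). The cofactor gene pqqD2 was at least 10.5-fold higher, with a signal at the floor on the control array, and pqqE was not resolved. The gene pqqD1, with the same product description and named after its value was seen, was detected on both arrays at -0.27. The glucose dehydrogenase gene gcd had -3.13. The regulator gene glpR, annotated as a glycerol-3-phosphate regulon repressor and caught by the list's pattern, was at least 2.42-fold lower.

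Of 11 polyamine genes 3 were lower and 2 higher (median -0.38, percentile 16.7). The binding protein gene PP_3147 was at least 6.40-fold higher, PP_2195 was not resolved, and PP_5341 and potG had -1.17 and -1.13. Of 7 polyhydroxyalkanoate genes, for storage polyester, 2 were lower (median 0.04, percentile 51.3): PP_5008 at -1.13 and phaC at -1.05. The probes of phaC disagreed, with 0.53 on the specific probe and -2.63 on the cross-hybridising one. Of 30 phage and transposon genes 10 were higher and 2 lower (median 0.33, percentile 78.1), with gpI at -1.39 and PP_3870 at -1.25, and PP_5405 and PP_2841 not resolved. Of the 10 rises 3 were detected on both arrays and 1 more had a bound over 2-fold. These were gpW (1.86), PP_0014 (1.73), PP_3066 (1.62) and PP_3500 (a log2 bound of 1.52), named after their values were seen.

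**Figure D3:**
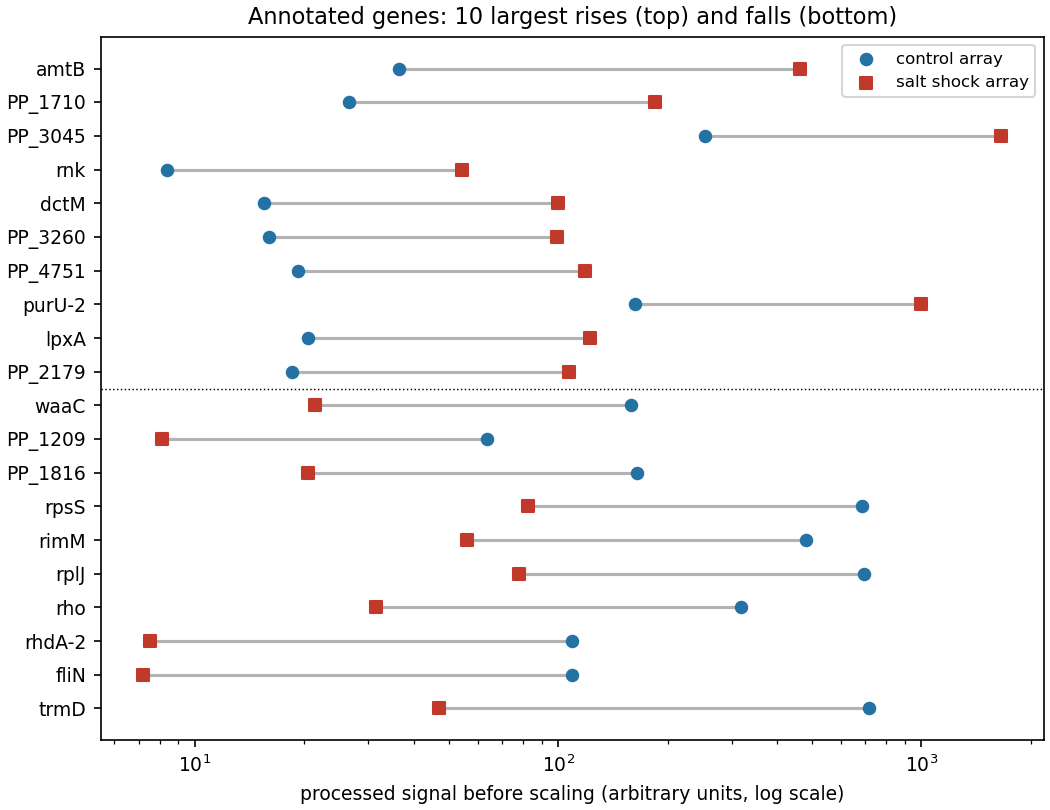
Processed signal before scaling (x axis, log scale) on the control array (circles) and the salt shock array (squares) for the 10 largest rises (top) and 10 largest falls (bottom) among annotated genes detected on both arrays, 1 array per group. The signal of amtB rose from 36.5 to 462 and that of trmD fell from 718 to 46.8.

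The other large rises among annotated genes detected on both arrays were those of PP_1710 (a permease, 2.39, on a probe with a listed next match of 95.7% identity), dctM (a dicarboxylate carrier, 2.28) and PP_4751 (an ATP-binding subunit of an amino acid transporter, 2.21). Also among them were PP_3045 (a ClpP-type protease in a phage region, 2.30, from 254 to 1654), rnk (a nucleoside diphosphate kinase regulator, 2.29), PP_3260 (a DNA ligase, 2.22), purU-2 (formyltetrahydrofolate deformylase, 2.21), lpxA (the first step of lipid A synthesis, 2.17) and PP_2179 (a peptidase, 2.12). Among annotated genes, the largest bounds belonged to PP_0312, an electron transfer flavoprotein gene at least 13.4-fold higher, then PP_2041 (11.8-fold), PP_3211 (11.5-fold), pqqD2 and PP_3236 (6.89-fold, on a probe with a listed next match of 92.0% identity). Downward they were PP_3349, a transporter gene at least 56.2-fold lower, trpG, of tryptophan synthesis (23.1-fold), PP_3541 (11.4-fold), ltg (10.95-fold) and PP_5147 (10.4-fold). PP_2702, at least 12.96-fold lower, was not ranked here because its product description is hypothetical.

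In all, 7 of the 30 lists had medians below percentile 2.5, and none lay as far above the random medians. The lists of universal stress proteins and DNA repair, at 2.21 and 2.46, sat at that edge, and with ribosomal proteins set to 0 their medians turned by construction to 0.85 and 1.98. Each direction rests on 1 culture and 1 array per group, so differences between flasks, RNA preparations or arrays are part of every ratio. The SD between probes of a gene was 0.81, or 0.55 without phaC, against 0.95 over all genes detected on both arrays, and each pair set a specific probe against a cross-hybridising one.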

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

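The alternatives that used bounds, the authors' deposited fold or the 75th percentile of probes detected on both arrays were chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. Normexp was not run. The scalings moved the median log2 ratio of all genes from 0.07 to -0.02 (median of all probes), 0.26 (centred on genes detected on both), 0.40 (75th percentile of those probes) and 0.48 (none), and to 2.61 with ribosomal proteins at 0. The lists below percentile 2.5 numbered 5 to 8 under the 20 alternatives that apply to lists. Over the settings of scaling, filter, floor, trend and bounds, apart from ribosomal centring, ribosomal proteins kept medians of -2.63 to -1.07, flagella -1.62 to -0.43, ATP synthase -1.50 to -1.0019 and aminoacyl-tRNA synthetases -0.87 to -0.37, while the tricarboxylic acid cycle reached percentile 8.60 at its highest. Signal over background limits the dim genes: most rises by signal had no bound of 2-fold.

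Counts that moved by over 1.5 times were as follows. Genes at least 2-fold lower numbered 220 without scaling, and 2064 were higher and 24 lower with ribosomal proteins at 0. Higher genes numbered 144 among those detected on both arrays, 260 after a trend on signal was removed, and 179 with bounds. At 1.5-fold 548 genes were lower, and at 4-fold 105 were higher and 115 lower, as fewer or more genes pass by construction. The count of lists above the central 95% of random medians was 1 with signals above the array median, and 1 with the brightest probe of a gene, both times the porin list. Otherwise the cause was not tested.

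Setting the ribosomal list to 0 adds one constant to every ratio, and so by construction turned lists and genes from lower to higher. The constant moves the random lists too, so percentiles stayed close. They were 0.0 for flagella, 0.25 for ATP synthase, 0.40 for aminoacyl-tRNA synthetases and 1.18 for the tricarboxylic acid cycle. The list medians became 0.85 (osmotic and universal stress proteins), 1.76 (aminoacyl-tRNA synthetases), 1.13 (ATP synthase), 2.03 (tricarboxylic acid cycle), 1.70 (flagella) and 1.98 (DNA repair), and among lists inside the random range 1.79 (translation factors), 1.79 (chemotaxis) and 2.18 (peptidoglycan and cell division), with every other negative median but that of ribosomal proteins positive too. The genes became PP_0869 1.24, PP_4431 1.46, betB 1.54, PP_3288 0.79, PP_2187 0.85, sodB 1.08, rpoD 0.43, fliA 0.59, nusA 0.0236, fusA 0.33, serS 0.0283, ileS 1.06, atpB 0.59, nuoA 0.89, nuoB 0.90, PP_1371 0.0911, PP_0350 0.30, PP_4137 1.09, ttg2A 1.00, PP_0589 1.24, PP_1131 1.44, algB 0.76, PP_4971 0.18, ftsQ 0.64, accB 0.68, accD 0.83, PP_5184 0.21, uvrA 0.26, recA 1.51, glpR 0.48, PP_5008 1.41, phaC 1.49, PP_5341 1.37, potG 1.41, gpI 1.15 and PP_3870 1.29. The universal stress list turned to 0.74 among genes detected on both arrays and to 0.41 with signals above the array median, because other members then counted. Removing a trend on mean signal turned 8 dim genes from higher to lower, and the cause was not tested: PP_3953 -0.10, rpmE -0.23, PP_0676 -0.31, metG -0.15, PP_2335 -0.30, leuA -0.39, PP_2643 -0.31 and proC-1 -0.33. Across the alternatives, 1738 values of named genes and 482 list medians stayed within the error used for them, while 148 and 106 moved further without counting as reversed, and lists inside the random range changed sign among these.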

Other observations

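Ontology terms, windows, the unscaled detection limit and the neighbour test outside the 5 lists were chosen only after the report's results were seen. The bounds that decide the other tests were set before their results were seen, except that the neighbour tests were first run with plus-strand pairs and then with both strands.

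Among 83 ontology terms with at least 10 measured genes, 11 had medians below the central 95% of matched random lists and 2 above it, where 4.15 outside would occur by chance for independent terms. The term for fatty acid synthesis was lower (5 of 10 genes at least 2-fold lower, median -0.86, percentile 1.54), whereas the report's wider list with membrane lipids was not with all measured genes. The term for chemotaxis (13 genes) lay at percentile 1.79, below the report's list at 6.23. The term for DNA repair (18 genes, 6 higher and 1 lower) had a median of 0.54 at percentile 69.4, or 0.05 in the 8 genes detected on both arrays, against -0.56 in the report's list. GTP binding was lower (4 of 14, median -0.77, percentile 0.57), and transporter activity lay inside the random range (percentile 45.0). The higher terms were both for sensor kinases, with medians of 0.64 (35 genes, percentile 99.4) and 0.59 (30 genes, percentile 98.1), but the median was 0.08 in the members of either term detected on both arrays.

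Along the chromosome, the runs of 10 measured genes with the lowest medians lay in the ribosomal protein cluster, from PP_0443 to PP_0465 (535133 to 556376, median -2.95) and from PP_0466 to PP_0477 (556397 to 562257, median -2.26), with genes of 1 array at their bounds. No shuffle of gene order among 2000 gave a run as low. The first run also holds rpoB and rpoC, the RNA polymerase genes, named here after their values were seen. The highest run, PP_0078 to PP_0104 with trpA (89315 to 111569), had a median of 0.81, which 33.8% of shuffles reached.

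More probes were detected on the salt shock array alone (568) than on the control array alone (92), a ratio of 6.17. With 1 limit on unscaled signal the ratio was 4.49 (exact binomial interval 3.63 to 5.60), which argues against a different limit of the flag as the whole cause. With 1 limit in scaled units it was 0.788 (0.652 to 0.952), but scaling itself brings the numbers passing that limit close together (1705 and 1651), so this value decides nothing. Whether salt or labelling made the salt shock array brighter was not tested. The GC content of the probes gave an area under the curve of 0.562 (0.498 to 0.627), and an effect of base composition cannot be told apart from none because that interval passes the bound of 0.6 set for it.

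The 5 lists for ribosomal proteins, aminoacyl-tRNA synthetases, ATP synthase, the tricarboxylic acid cycle and flagella (93 genes) had a median of -1.41. It was -1.25 (bootstrap interval -1.71 to -0.88) after a smooth trend on mean signal was removed, -1.54 (-2.05 to -1.10) after one on probe GC content, and at its highest -1.0019 (-1.40 to -0.61) over 4 scalings that used no gene list. All 3 values lie below the bound of -0.25. For probe GC content, this argues against it as the whole cause. The lists were picked as low against random lists matched on mean signal, so the value after the signal trend decides nothing. Leaving out the scaling only takes the constant of -0.406 off every ratio. That value shows that none of the 4 scalings brought the median to the bound, and no more. The intervals resample genes as independent although adjacent genes moved together, so they are likely too narrow. The 5 lists were kept for both their theme and their low percentiles. Lists inside the random range, such as translation factors (percentile 2.94), chemotaxis (6.23) and NADH dehydrogenase and terminal oxidases (10.4), were left out. The values therefore do not describe growth and motility genes as a class. A lower share of the 5 lists' transcripts after salt shock is a hypothesis that these values leave standing. It stands as a share relative to other transcripts, since with ribosomal proteins set to 0 the other 4 medians are positive by construction. A different growth state of the 2 flasks could give the same values, and 1 culture per group cannot part these.

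Genes that sit in 1 transcript should move together, and noise of single probes should not. Over 228 adjacent same-strand pairs (gap of at most 50 bp, detected on both arrays) the log2 ratios correlated at 0.426, against 0.135 at the upper end of the central 95% of 2000 shuffles, at -0.02 over 149 neighbours on opposite strands, and at 0.246 over the 208 pairs outside the 5 lists. Neighbours of genes at least 2-fold lower had a median -0.94 (-1.42 to -0.57) from that of all such neighbours, which argues against probe noise as the whole cause of the falls taken as one set, though on the plus strand alone the interval reached 0.11 (-0.61, from -1.42) and on the minus strand it did not (-0.94, -1.64 to -0.68). Outside the 5 lists the difference was -0.29 (-0.68 to 0.03), so for those falls probe noise cannot be told apart from change, since the interval crosses the bound of -0.1. Neighbours of genes at least 2-fold higher differed by 0.30 (0.07 to 0.56), so for the rises probe noise cannot be told apart from change, since the interval crosses the bound of 0.1. The intervals over neighbours resample each value as independent, although each pair entered in both directions and a gene can sit in more than 1 pair. They are therefore likely too narrow.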
